A study of Mus musculus with 9 samples.

How the data were processed

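RNA was extracted from mouse chondrocytes with TRIzol, and libraries of polyadenylated RNA were prepared with the VAHTS Universal V6 kit, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene for the 9 libraries, with gene symbols and Entrez identifiers. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build mm10, without versions; the gene annotation and the strand setting of the counting are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical gene copies, may therefore be shared or left out in ways that the counts do not show. Values in the deposited table were whole numbers with totals that differed between libraries, as raw counts do. Counts came to 40514918, 40324998 and 39405472 in control replicates 1 to 3, 39680072, 39811208 and 37224985 in inflammation replicates 1 to 3, and 38973497, 37336981 and 38451227 in Cu SAC replicates 1 to 3. No row lacked a gene name.

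Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples through the column names that the descriptions give. The table held 27596 genes, 18674 of them marked protein-coding. Identifiers were matched to the RefSeq gene table of GRCm38.p6, where 26633 were found, and coordinates come from that table. Genes were kept with filterByExpr (edgeR 4.0.16, minimum count 10), which left 16134. Counts were scaled by TMM, and CPM values and folds are on that scale. All 9 libraries entered 1 quasi-likelihood fit (glmQLFit with robust estimation, group as the only term, 6 residual degrees of freedom), and each contrast was tested with glmQLFTest in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold, and every adjusted p in the text comes from edgeR unless another tool is named. Standard errors were taken as the absolute log2 fold change divided by the square root of F. Group means carry the SD over 3 libraries.

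Before the data were examined, 35 gene lists were fixed for cartilage biology, inflammation, energy and NAD+ metabolism, metal handling, stress and growth, and other cell types; 34 had at least 5 tested members, and the list of erythroid markers had 3. Of 726 list entries 722 were found in the table. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the correlation estimated from the data and fry as alternatives. Camera called 11, 12 and 16 lists for inflammation against control, Cu SAC against inflammation and Cu SAC against control. None of these calls held with an estimated correlation. Fry called 6, 4 and 13 lists. The first were cartilage matrix, protease inhibitors, proliferation and adipocyte markers (fry adjusted p = 0.0102 each) and p53 (0.0342). Cell death genes, which camera had not called, were the last of them (0.0439). The second were NF-κB and p53 (0.0482 each), chemokines (0.0438) and glycolysis (0.0416). The third included NF-κB, chemokines, cholesterol synthesis and proliferation (0.00811 each). The named genes were also fixed by rule: per comparison, the 6 highest and 6 lowest fold changes among called genes with no overlap between the groups, at least 5 CPM in the higher group and no predicted or clone name; up to 4 members with the smallest p of each list called by camera and of 6 lists in any case; and a set of index genes whether or not they passed. Some list members and index genes are left out of the text for length. The value of 1 further list member is not reported.

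Replicate numbers came from the titles, which do not say that a number marks a shared animal, day or batch. Deviations from the group means of same-numbered libraries correlated at 0.37, 0.34 and 0.6 between inflammation and control, so those numbers were taken as pairs. Unlike numbers 1 and 2 correlated about as highly, at 0.35 and 0.32. Deviations cancel out within a group, so replicates 1 and 2 had to correlate once the replicate 3 libraries deviated alike. The check therefore shows that likeness of replicate 3 and cannot establish pairs for replicates 1 and 2. Control replicates 1 and 2 were nearly alike, so this check cannot tell which of them pairs with which inflammation library. The counts of calls with the block had been seen together with these correlations, but the decision followed a criterion set in advance, that every correlation exceed 0.1. The planned fit without the block stays the one reported.

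Alternatives comprised other size factors (median of ratios, upper quartile), DESeq2 1.42.0 (on all 27596 genes, with its own filtering), limma-voom, no low-count filter or a stricter one (at least 1 CPM in 3 libraries and a mean count of 20), a fit of only the groups compared, replicate number as a block, no mitochondrial genome genes, a minimum fold of 2, and each library left out in turn. Leaving out 1 library lets a group of 2 share the spread estimated over all groups. After the data were seen, fits without 2 libraries together (control 3 and inflammation 3, inflammation 3 and Cu SAC 1, and control 3 and Cu SAC 1 for the comparisons in order), with 1 surrogate variable (sva 3.50.0), with DESeq2 on the filtered genes, and with a replicate block in the 6 libraries of the first comparison were added. Figures were drawn with matplotlib 3.10.9.

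The steps were tested on simulated data drawn from the real genes' means, dispersions and library sizes, with 200 genes changed. For inflammation against control, 36% of 2-fold and 79.6% of 4-fold changes were called, and 8.8% of calls were false; the step ran on 15822 genes. For Cu SAC against inflammation these values were 31.6%, 73% and 5.5% over 15814 genes, and for Cu SAC against control 44.9%, 71% and 2.5% over 15826 genes. A list raised 2-fold was called in each simulated comparison with the preset and with the estimated correlation, and 0 of the other lists were. Genes were drawn independently here. In the real data the estimated correlation for inflammation against control was 0.429 in the proliferation list and 0.808 in the ribosomal protein list. The simulation thus does not show how either setting performs on lists whose genes vary together. The share of false calls for inflammation against control, 8.8%, lay above the 5% at which genes were called. Chance values for comparisons that share libraries came from 50 simulated data sets with no effect (20 for the shared controls), in which genes vary independently with 1 dispersion per gene for all groups; the real libraries also vary in many genes together, which these simulations leave out. These data sets called 0.1 genes on average for inflammation against control (0.2 in the 20), so few calls could be shared in them and their counts do not show how many shared calls come from shared libraries.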

Results

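Gene expression was measured by RNA sequencing of polyadenylated RNA from mouse chondrocytes, the cells that make and maintain cartilage. The 9 libraries fell into 3 groups of 3: an untreated control group, a group labelled as inflammation, and a group labelled as inflammation with Cu SAC, an agent that the labels do not describe. The library names point to IL-1β, a cytokine used to provoke inflammation in cartilage cells, as the inflammatory stimulus. No dose or time was given in the sources used here. The series title speaks of raised NAD+ production, so genes of NAD+ and energy metabolism were examined along with those of inflammation and cartilage matrix. Total counts per library ranged from 37224985 to 40514918 over 27596 genes, of which 16134 had enough counts to be tested. The labels call the replicates biological but do not say whether they came from separate animals or cultures, so p-values measure only the spread between these libraries.

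Replicates did not lie equally close together. Control replicates 1 and 2 had a biological coefficient of variation of 0.0448 between them, and inflammation replicates 1 and 2 one of 0.0913. Control replicate 3 differed from the other control libraries by 0.263 and 0.26, and inflammation replicate 3 from the other inflammation libraries by 0.303 and 0.319. Cu SAC replicate 1 differed from replicates 2 and 3 by 0.324 and 0.224, and those 2 from each other by 0.225, so this measure set no Cu SAC library apart. Control replicates 1 and 2 still differed by more than sampling noise, with a chi-square per degree of freedom of 5.29, and were kept as separate samples. That value was 132 and 125 between them and control replicate 3. It cannot tell separate cultures from repeat libraries of the same culture. Calls for inflammation against control fell from 430 to 88 and 77 without control replicates 1 and 2, so they lean on both. The first principal component held 57% of the variance and placed control replicate 3 and inflammation replicate 3 away from their groups, towards the Cu SAC libraries, and Cu SAC replicate 1 at 21.76 against 95.14 and 73.48 for the other Cu SAC libraries.

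**Figure D1:**
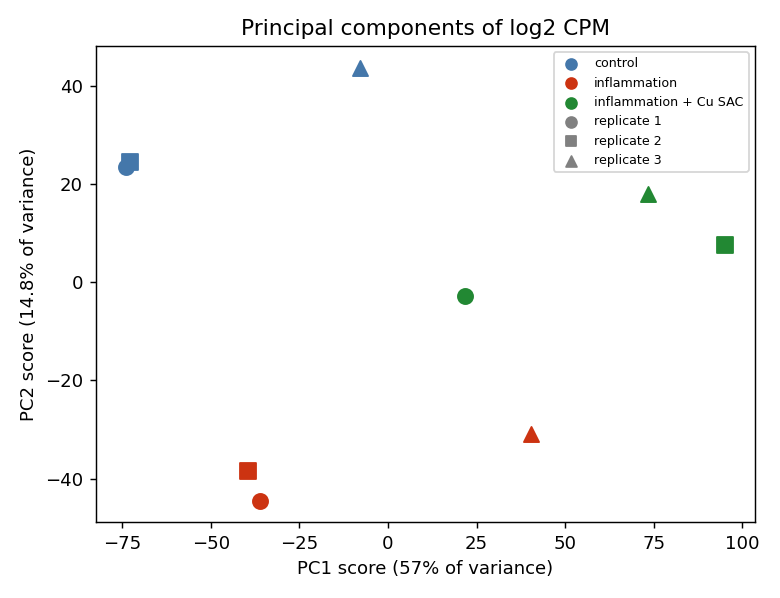
Scores of the 9 libraries on the first and second principal components of log2 CPM (57% and 14.8% of the variance); colour gives the group and marker shape the replicate number. Control replicates 1 and 2 lie almost on one another at -74.06 and -72.98 on the first component, while control replicate 3 lies at -7.99 and inflammation replicate 3 at 40.42.

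The first comparison asked how the inflammation group differed from control. Of 21 genes in the list of p53 targets and senescence genes 5 rose in the inflammation group and 1 fell, and 19 of 28 cell-cycle genes fell. The transcription factor p53 acts in the DNA damage response. Pmaip1, which encodes the pro-apoptotic protein NOXA, rose 6.65-fold, from 2.26 ± 0.591 to 15.1 ± 1.43 CPM (SD, n = 3 each). Cfd (complement factor D, or adipsin) and Adipoq (adiponectin), both products of fat cells, fell by 4.09 and 3.08 on the log2 scale. Of 25 genes of the cartilage matrix list 7 fell and 1 rose. In all, 228 genes were higher and 202 lower among the 16134 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 2655 had an unadjusted p under 0.05. The groups did not overlap in 4182 genes, where chance gives 10% of the genes tested, and the 430 called genes were among them.

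In the p53 and senescence list 15 genes did not pass the test, and 8 were higher and 2 lower when adjusted over the list alone. Mdm2, whose product degrades p53, rose 2.44-fold (log2 fold change 1.29, SE 0.1, adjusted p = 0.0013), from 106 ± 6.85 to 258 ± 12 CPM. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose 2.86-fold (SE 0.18 on the log2 scale), Ccng1 2.99-fold and Eda2r 3.84-fold. The fifth that rose was Btg2 and the one that fell was Lmnb1, a nuclear lamina gene, both named after their values were seen. The list as a whole was higher by camera (adjusted p = 1.25e-06), a call that was lost with an estimated correlation between genes (adjusted p = 0.249 with an estimated correlation). In the proliferation list 19 of 28 members fell and none rose; 23 were lower and 1 higher adjusted over the list alone. Tpx2, Kif11, Ccna2 and Cenpe, which act in mitosis or drive the cell cycle, fell by 1.64, 1.84, 1.7 and 2.18 on the log2 scale. Camera gave the list an adjusted p of 8.49e-34, against an adjusted p = 0.107 with an estimated correlation.

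Among 25 cartilage matrix genes, Ucma, Comp and Cilp were among the 7 that fell, by 1.28, 1.22 and 2.05 on the log2 scale, and Prg4, which encodes the joint lubricant lubricin, rose 2.29-fold; 15 were lower and 1 higher adjusted over the list alone (camera adjusted p = 8.57e-12, adjusted p = 0.107 with an estimated correlation). Col2a1 and Acan, the main collagen and proteoglycan genes of cartilage, had log2 fold changes of -0.6 (SE 0.29, adjusted p = 0.35) and -0.36 (SE 0.48, adjusted p = 0.76). Both were lower in the inflammation library in 3 of 3 same-numbered pairs. With replicate number as a block in a fit of these 6 libraries both were called lower (-0.66, adjusted p = 0.022, and -0.44, adjusted p = 0.034). Replicates 1 and 2 lay close together in control (coefficient of variation 0.0448) and in inflammation (0.0913), so pairs 1 and 2 nearly repeat each other. The 3 pairs are therefore not 3 independent observations, and the blocked adjusted p draw on that closeness. Of the 7 measured adipocyte markers 5 fell, among them Fabp4 at 245 ± 19.3 CPM in control and 45 ± 3.7 CPM in the inflammation group, and 6 were lower adjusted over the list alone (camera adjusted p = 1.04e-25, adjusted p = 0.0867 with an estimated correlation). Of 16 macrophage markers 3 fell, namely Lyz2, Itgam and Csf1r (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000251, adjusted p = 0.454 with an estimated correlation). The median of this list was 0.73 and 0.78 in control replicates 1 and 2. In control replicate 3 it was -0.18, within the range of the inflammation libraries (-0.33 to 0.02). Over the 34 lists, control and inflammation medians did not overlap in 12, and the gap exceeded the larger SD in 6. Of 10 protease inhibitors Serpine2 rose 2.04-fold (3 higher adjusted over the list alone; camera adjusted p = 0.00211, adjusted p = 0.249 with an estimated correlation).

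Of 24 genes of the unfolded protein and amino acid responses, Phgdh and Mthfd2, enzymes of serine and folate metabolism, fell by 0.86 and 0.95 on the log2 scale (9 lower adjusted over the list alone; camera adjusted p = 1.02e-05, adjusted p = 0.461 with an estimated correlation). Of 20 cholesterol synthesis genes Dhcr7 fell by 0.7 on the log2 scale (5 lower adjusted over the list alone; camera adjusted p = 6.54e-06, adjusted p = 0.463 with an estimated correlation). Camera also called 14 muscle markers lower (adjusted p = 8.75e-05, adjusted p = 0.49 with an estimated correlation) and 36 ribosomal protein genes lower (adjusted p = 0.00439, adjusted p = 0.7 with an estimated correlation). It called 20 interferon response genes higher (adjusted p = 0.0116, adjusted p = 0.7 with an estimated correlation). In these 3 lists edgeR called 0 genes singly, while 7, 3 and 3 had an unadjusted p under 0.05, DESeq2 called 1, 0 and 2 and limma-voom 0 in each. The ribosomal call was lost without inflammation replicate 3 (adjusted p = 0.275) and the interferon call without inflammation replicate 1 (adjusted p = 0.592). List medians of control and inflammation libraries overlapped for the cholesterol synthesis, ribosomal protein and interferon lists. For the unfolded protein and muscle lists they did not (gaps of 0.02 and 0.35).

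Of 28 genes of the NF-κB inflammatory list, Icam1 rose 2.17-fold and C3 fell by 1.87 on the log2 scale, while 3 were higher and 1 lower adjusted over the list alone; camera did not call the list (adjusted p = 0.203). Log2 fold changes of commonly used inflammation markers did not pass the test: Ptgs2 2.11 (SE 1.39), Ccl2 1.44 (SE 0.91), Nos2 0.57 (SE 0.9) and Mmp3 0.49 (SE 0.81). Each of these was negative, and still not called, without inflammation replicate 3 (Ptgs2 -0.57, Ccl2 -0.11, Nos2 -0.56, Mmp3 -0.15). That fit keeps control replicate 3, which the numbers pair with inflammation replicate 3. Within same-numbered pairs Ptgs2, Ccl2 and Mmp3 were higher in the inflammation library in 3 of 3 pairs and Nos2 in 1 of 3. Here too pairs 1 and 2 nearly repeat each other, which limits these counts and the blocked adjusted p. In a fit of these 6 libraries with replicate number as a block, Ccl2 (log2 fold change 1.24, adjusted p = 0.0024) and Mmp3 (0.46, adjusted p = 0.035) were called higher, Ptgs2 was not (1.26, adjusted p = 0.073), and Nos2 was not tested. Ptgs2 stood at 36.2 ± 52.9 CPM in the inflammation group, a spread larger than its mean. Of 18 matrix proteases, Adamts4 and Adamts12 fell by 1.16 and 1.85 on the log2 scale, and Mmp13 had a log2 fold change of -0.78 (SE 0.43, adjusted p = 0.42), was lower in 3 of 3 pairs and was called with the block (-0.77, adjusted p = 0.021). None of 17 NAD+ synthesis genes passed edgeR's test, where 1 had an unadjusted p under 0.05 and DESeq2 and limma-voom each called 0. Among 54 nuclear genes of oxidative phosphorylation edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom.

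Among called genes whose groups did not overlap and that reached 5 CPM, the 6 with the highest and the 6 with the lowest fold changes were, in that order, Svop, Ces2e, St14, Cox6b2, Tbc1d8 and Pmaip1, and Retn, Adrb3, Cfd, Ppp1r1a, Slc36a2 and Adipoq. In mm10, which is GRCm38, Pmaip1 (Entrez 58801) lies on chromosome 18 from 66458604 to 66465558, Cfd (11537) on chromosome 10 from 79890853 to 79892655 and Adipoq (11450) on chromosome 16 from 23146536 to 23157968. Retn, which encodes resistin, fell by 4.7 on the log2 scale. Adrb3, the β3-adrenergic receptor of fat cells, fell by 4.21. Ces2e rose 13.7-fold from 0.635 ± 0.373 CPM. Of the 37 named genes called in this comparison, 19 kept an adjusted p under 0.05 whichever of the 6 libraries was left out, among them Pmaip1, Mdm2, Cdkn1a, Ccng1, Eda2r, Fabp4, Cfd, Adipoq, Retn, Icam1, Serpine2 and Tpx2. Svop, Cox6b2, Mthfd2 and Csf1r kept it in 0 of these 6 settings, where their adjusted p ranged from 0.05 to 0.21. Adrb3 was lost without inflammation replicate 2 (adjusted p = 0.05), and Cilp without inflammation replicates 1 and 2 (at most 0.078). Ucma was lost without control replicates 1 and 2 and inflammation replicate 1 (at most 0.067), Ppp1r1a without control replicates 1 and 2 and inflammation replicate 2 (at most 0.071), and Comp without control replicate 2 and inflammation replicates 1 and 3 (at most 0.075). Lyz2 was lost without control replicates 1 and 2 and inflammation replicates 1 and 2 (at most 0.082), and Adamts4 without control replicates 1 and 2 and inflammation replicates 1 and 3 (at most 0.091). Prg4 kept its call only without inflammation replicate 2 (elsewhere at most 0.095). C3, Slc36a2, Itgam, Adamts12 and Dhcr7 kept theirs only without control replicate 3, with adjusted p elsewhere of at most 0.084, 0.082, 0.13, 0.16 and 0.14.

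The count of 430 genes was 88, 77 and 306 without control replicates 1, 2 and 3, and 97, 119 and 222 without inflammation replicates 1, 2 and 3. With replicate number as a block in a fit of these 6 libraries it was 2227, and with the block in a fit of all 9 libraries 611. DESeq2 called 1038. The block of 6 libraries rests on the replicate 3 libraries deviating alike and on the closeness of replicates 1 and 2 in each group. Its calls are thus not those of 3 independent pairs. Of the 23 genes named in advance, Adamts4 was called without the block; of the 22 tested in the blocked fit of 6 libraries 2 were called higher (Ccl2 and Mmp3) and 7 lower. Those lower were Mt2 (-1.85, adjusted p = 0.00034) and Mt1 (-1.11, adjusted p = 0.0023), with Adamts4, Mmp13, Col2a1, Acan and Sox9 (-0.34, adjusted p = 0.042), and each of the 7 was lower in 3 of 3 pairs.

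**Figure D2:**
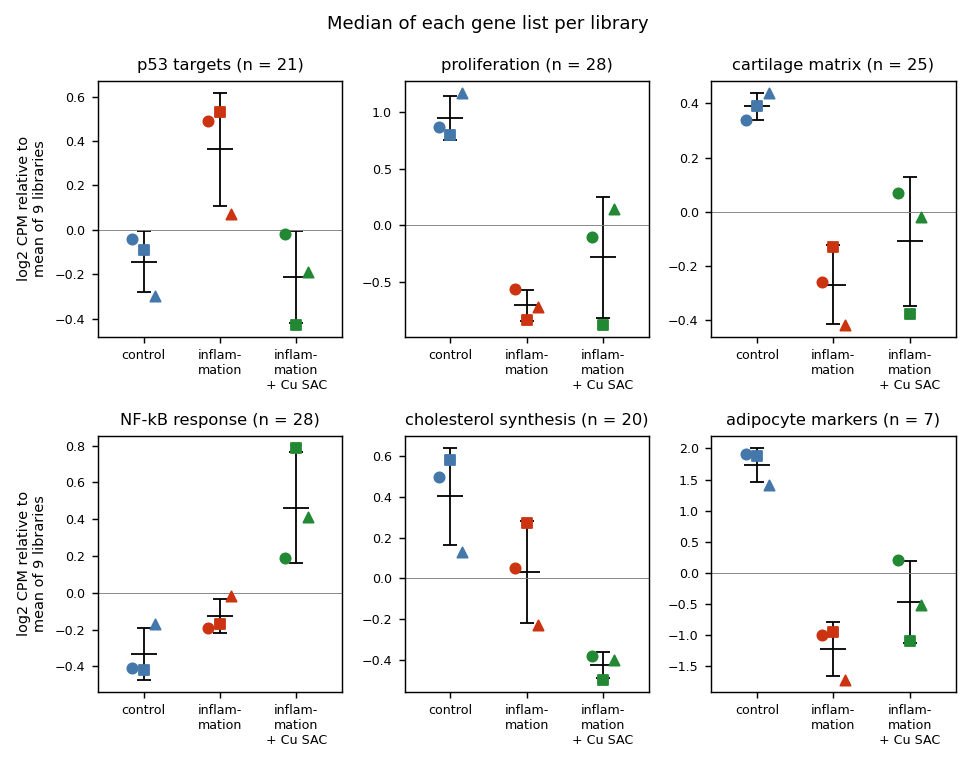
Median log2 CPM, relative to each gene's mean over the 9 libraries, of 6 gene lists; each marker is a library (circle, square and triangle for replicates 1, 2 and 3) and bars give the mean and SD of 3 libraries, with n in each title the number of genes. The p53 list lies between 0.07 and 0.53 in the inflammation libraries and between -0.3 and -0.04 in the controls, while the NF-κB list is highest in the Cu SAC libraries, from 0.19 to 0.79.

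The second comparison asked what Cu SAC changed in inflamed cells. Of 16134 genes tested 8 passed, of which 5 were higher and 3 lower with Cu SAC. Apod (apolipoprotein D) rose 9.04-fold, Hp (haptoglobin) 4.11-fold from 15 ± 1.38 to 61.7 ± 7.39 CPM, Cfb (complement factor B) 3.75-fold from 18.9 ± 1.92 to 70.7 ± 11.6 CPM, and Saa3 (serum amyloid A3) 5.49-fold from 7.15 ± 0.978 to 39.3 ± 9.1 CPM (SD, n = 3 each). Dpt, which encodes the matrix protein dermatopontin, rose 2.29-fold. Pmaip1 fell by 2 on the log2 scale (SE 0.23, adjusted p = 0.019), Ccn3 by 1.42 (SE 0.18, adjusted p = 0.046), and the anion transporter gene Slc26a7 by 3.05. Slc26a7, below 5 CPM in both groups, was outside the rule for named genes and was named after its values were seen.

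In mm10, Hp (Entrez 15439) lies on chromosome 8 from 109575128 to 109579172, Cfb (14962) on chromosome 17 from 34856374 to 34862514, and Saa3 (20210) on chromosome 7 from 46711998 to 46719615. Saa3 belongs to a family of similar genes, so its counts are uncertain where reads could be shared between members. Hp and Cfb kept their calls whichever library was left out, with adjusted p from 0.0029 to 0.018. Saa3 lost its call without inflammation replicate 1 (adjusted p = 0.06), and Apod, Dpt, Pmaip1 and Ccn3 lost theirs without inflammation replicate 1 or 2 or Cu SAC replicate 3, Ccn3 also without Cu SAC replicate 2.

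**Figure D3:**
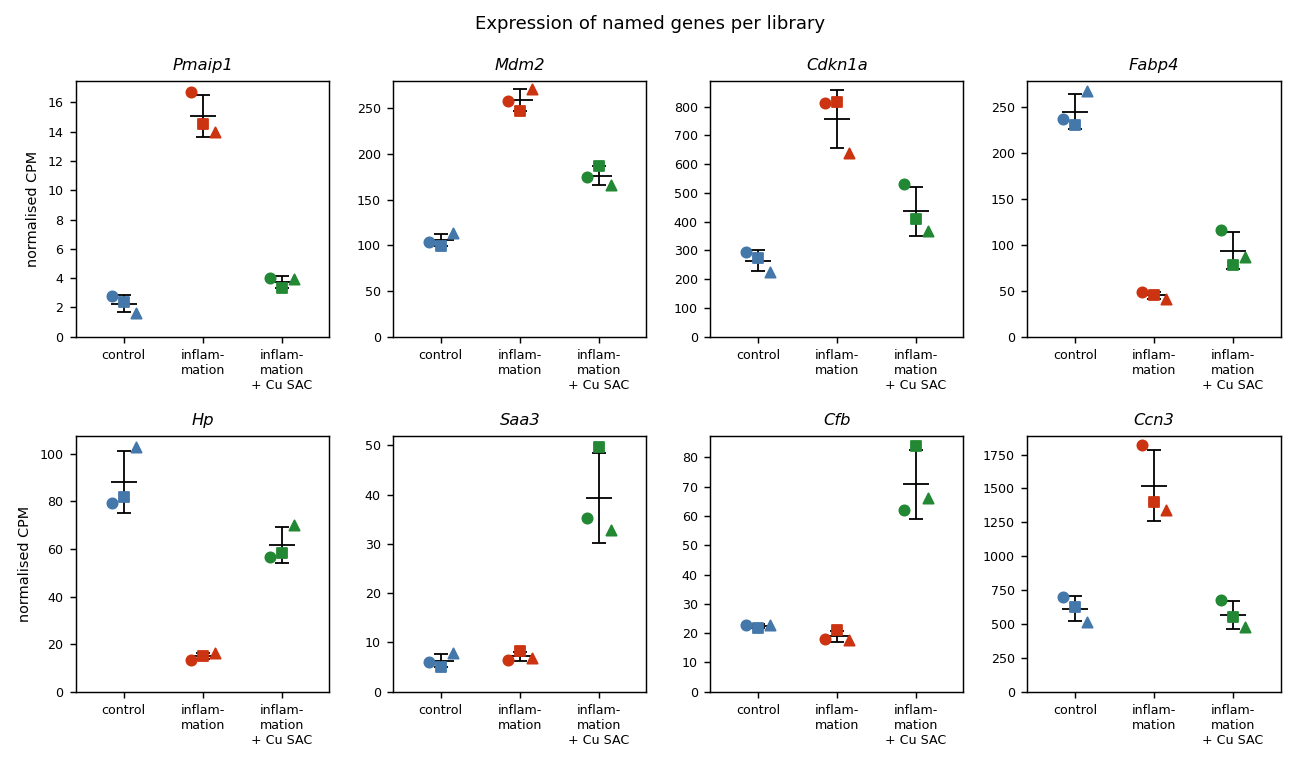
Normalised CPM of 8 genes in each library (circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of 3 libraries per group; axes start at 0. Hp stood at 15 CPM on average in the inflammation group and 61.7 CPM with Cu SAC, and Pmaip1 at 15.1 and 3.75 CPM.

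In the fixed lists, edgeR called only Saa3 among 28 NF-κB genes and Dpt among 14 fibroblast and synovial markers. Adjusted over the list alone, 11 NF-κB genes were higher and 1 lower, 8 p53 and senescence genes were lower, and 12 of 20 cholesterol synthesis genes were lower. Camera called the NF-κB list higher (adjusted p = 7.57e-07; adjusted p = 0.36 with an estimated correlation) and the p53 list lower (adjusted p = 1.08e-05; adjusted p = 0.36 with an estimated correlation). Values for p53 list members were -1.16 for Ccng1 (SE 0.19, adjusted p = 0.079), -0.55 for Mdm2 (SE 0.1, adjusted p = 0.079) and -0.79 for Cdkn1a (SE 0.17, adjusted p = 0.087) on the log2 scale. For NF-κB genes they were 1.84 for C3, 1.6 for Lcn2 and 4.04 for Nos2, with adjusted p from 0.079 to 0.08. The cholesterol synthesis list was called lower (camera adjusted p = 1.08e-05; adjusted p = 0.676 with an estimated correlation) and the glycolysis list higher (camera adjusted p = 0.00492; adjusted p = 0.36 with an estimated correlation), with 8 glycolysis genes higher and 2 lower adjusted over the list alone. The glycolysis call was lost without inflammation replicate 3 (adjusted p = 0.067).

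Camera called 8 other lists, in which edgeR called 0 genes singly. Those called higher were chemokines (adjusted p = 0.00571, adjusted p = 0.36 with an estimated correlation; 3 of 16 higher adjusted over the list alone), proliferation (adjusted p = 0.00492, adjusted p = 0.806 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone), adipocyte markers (adjusted p = 0.00856, adjusted p = 0.806 with an estimated correlation; 3 of 7 higher and 1 lower adjusted over the list alone) and muscle markers (adjusted p = 0.00399, adjusted p = 0.806 with an estimated correlation). Those called lower were osteoblast markers (adjusted p = 0.00856, adjusted p = 0.414 with an estimated correlation; 4 of 9 lower adjusted over the list alone), matrix proteases (adjusted p = 0.00577, adjusted p = 0.414 with an estimated correlation; 3 lower and 1 higher adjusted over the list alone), ribosomal proteins (adjusted p = 0.0077, adjusted p = 0.824 with an estimated correlation) and the genes of the mitochondrial genome (adjusted p = 0.015, adjusted p = 0.806 with an estimated correlation). In the order given, 5, 13, 4, 3, 4, 8, 5 and 3 genes of these lists had an unadjusted p under 0.05, DESeq2 called 4, 6, 4, 1, 4, 5, 1 and 1, and limma-voom 0 in each. Leaving out libraries ended several of these calls. The adipocyte call was lost without inflammation replicate 3 (adjusted p = 0.162) and Cu SAC replicate 1 (0.247), and the proliferation call without Cu SAC replicates 1 (0.0775) and 3 (0.0811). The muscle call was lost without Cu SAC replicate 3 (0.203) and the ribosomal call without inflammation replicate 2 (0.253) and Cu SAC replicate 2 (0.476). The mitochondrial genome call was lost without inflammation replicate 3 (0.442), Cu SAC replicate 1 (0.118) and Cu SAC replicate 3 (0.101).

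Of 17 NAD+ synthesis genes edgeR called 0, with 4 at an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 0; camera gave the list an adjusted p of 0.389. Nampt, the rate-limiting enzyme of the NAD+ salvage pathway, had a log2 fold change of -0.7 (SE 0.22, adjusted p = 0.12). Of the 54 oxidative phosphorylation genes edgeR called 0, with 5 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and of 18 genes of metal and copper handling it called 0, with 4 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. The metal-binding metallothioneins Mt1 and Mt2 had log2 fold changes of -0.92 (SE 0.53) and 0 (SE 0.64). Acan had one of 1.99 (SE 0.5, adjusted p = 0.1), from 1030 ± 675 to 4090 ± 1240 CPM, and Mmp3 one of 3.1 (SE 0.86, adjusted p = 0.11), with 230 ± 248 CPM under Cu SAC.

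At an unadjusted p under 0.05 there were 3815 genes, 23.6% of those tested, and the groups did not overlap in 4088, where chance gives 10%. A split that set inflammation replicates 1 and 2 with Cu SAC replicate 1 against the rest of these libraries had 4358 genes at that p. The count of 3815 therefore cannot be read as a Cu SAC effect alone. Without Cu SAC replicate 1 edgeR called 1392 genes, without Cu SAC replicates 2 and 3 it called 15 and 3, and without inflammation replicates 1, 2 and 3 it called 2, 3 and 25; DESeq2 called 1570 and edgeR without a low-count filter 146.

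Of the 430 genes that differed between inflammation and control, 4 also changed with Cu SAC, each in the opposite direction: Hp and Dpt, which had fallen, rose, and Pmaip1 and Ccn3, which had risen, fell. Independent lists of these sizes would share 0.105 genes in opposite directions. In 50 simulations of groups with no effect that shared the inflammation libraries it was 0.04 on average and at most 1, but these called 0.1 genes on average in the first comparison, so this count says nothing of how many shared calls come from shared libraries. Across genes, which are not independent replicates, the correlation between both sets of log2 fold changes was -0.026, against -0.502 on average in the simulations, and the covariance was -0.0138 against -0.0885. Of the 430 genes 354, or 82.3%, had a Cu SAC fold change of the opposite sign. Among the 2655 genes with an unadjusted p under 0.05 in the first comparison it was 63.1%, against 88.6% on average in the simulations. Such genes passed by chance alone in the simulations, so most of them had to change sign. The real genes include some with a group difference, for which 88.6% and -0.502 are no measure of what shared libraries alone would give. These figures thus do not show whether Cu SAC moved genes back more or less than chance. Part of any opposite movement comes from the shared inflammation libraries. Without inflammation replicates 1, 2 and 3 the count of 4 became 1, 1 and 9, without control replicates 1, 2 and 3 it was 2 each time, and without Cu SAC replicates 1, 2 and 3 it was 103, 8 and 1; the correlation of inflammation and Cu SAC effects ran from -0.305 without inflammation replicate 3 to 0.193 without control replicate 3, and was 0.044 and -0.128 without Cu SAC replicates 1 and 2.

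**Figure D4:**
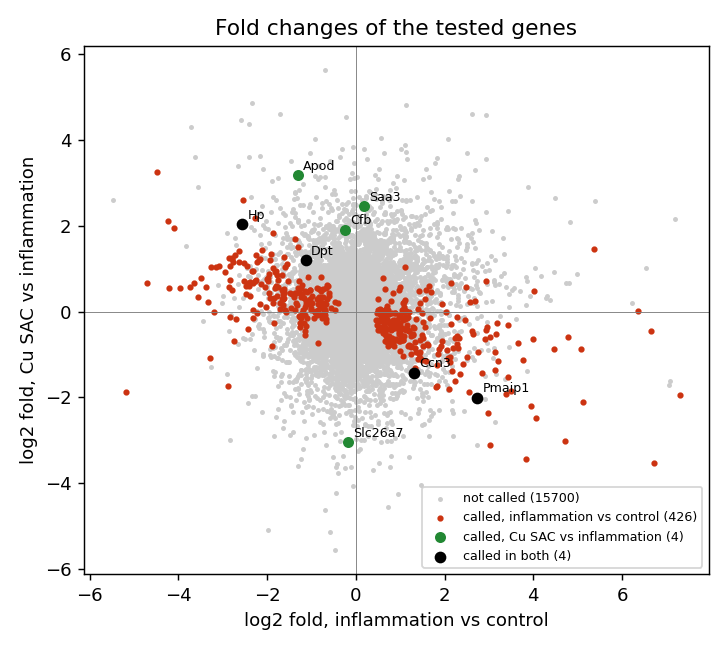
Log2 fold changes of the tested genes for inflammation against control (horizontal) and Cu SAC against inflammation (vertical), one point per gene. The 4 genes called in both comparisons (Hp, Dpt, Ccn3, Pmaip1) lie in the quadrants of opposite sign, and both axes contain the inflammation libraries.

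The third comparison set the Cu SAC group against untreated control. Of 28 NF-κB genes 12 rose and 0 fell (19 higher and 2 lower adjusted over the list alone), with Saa3 at 6.23-fold (SE 0.22 on the log2 scale) and Icam1 at 1.97-fold (SE 0.12). Of 16 chemokine genes 4 rose, namely Ccl5, Cxcl1, Ccl8 and Ccl7, by 30.6, 22.3, 16.5 and 8.69-fold; 9 were higher and 2 lower adjusted over the list alone. They stood at 5.3 ± 4.06, 12.8 ± 13.4, 5.79 ± 3.97 and 72.1 ± 27.4 CPM with Cu SAC, and control libraries held 1 to 15 counts of Ccl5, 13 to 27 of Cxcl1 and 6 to 27 of Ccl8. The folds depended on single libraries: Ccl5 ran from 17.5 without Cu SAC replicate 3 to 78.8 without control replicate 3, Cxcl1 from 9.22 without Cu SAC replicate 2 to 31.7 without Cu SAC replicate 1, Ccl8 from 9.97 without Cu SAC replicate 3 to 31.7 without control replicate 3, and Ccl7 from 6.88 without control replicate 2 to 16.1 without control replicate 3. edgeR called 1010 genes higher and 1075 lower of 16134 tested, with 5632 at an unadjusted p under 0.05. The groups did not overlap in 6436 genes, where chance gives 10%, and 2070 of these were called.

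Of 23 glycolysis genes 11 rose and 1 fell (13 and 3 adjusted over the list alone), among them Slc16a3, a lactate transporter, 2.03-fold and Pkm, pyruvate kinase, 2.17-fold. Of 20 cholesterol synthesis genes 15 fell (18 adjusted over the list alone), among them Insig1, Nsdhl and Cyp51 by 2, 1.46 and 1.4 on the log2 scale. In the proliferation list 13 of 28 fell (20 adjusted over the list alone). Camera called these 5 lists, with adjusted p of 1.9e-07 for NF-κB, 0.00528 for chemokines, 0.000297 for glycolysis, 1.78e-12 for cholesterol synthesis and 6.16e-11 for proliferation. With an estimated correlation the adjusted p was 0.233 for NF-κB, chemokines, glycolysis and cholesterol synthesis and 0.27 for proliferation.

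Cartilage matrix genes numbered 8 lower and 1 higher of 25 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000512, adjusted p = 0.299 with an estimated correlation). Col9a1 fell by 1.71 and Col2a1 by 1.17 on the log2 scale, and Prg4 rose 2.29-fold. Of 18 matrix proteases 6 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.000846, adjusted p = 0.236 with an estimated correlation), with Mmp14 and Adamts4 falling by 1.91 and 1.43 on the log2 scale and Mmp3 rising 12.1-fold from 19.1 ± 10.6 to 230 ± 248 CPM. Of 9 osteoblast markers 4 fell, among them Col1a1 and Ibsp (5 lower adjusted over the list alone; camera adjusted p = 0.000803, adjusted p = 0.233 with an estimated correlation). Of 7 adipocyte markers 6 fell, among them Fabp4, which fell by 1.39 on the log2 scale (7 lower adjusted over the list alone; camera adjusted p = 2.82e-09, adjusted p = 0.233 with an estimated correlation). Of 20 genes of TGF-β signalling and fibrosis 7 fell and 2 rose, in that order also adjusted over the list alone, with Col1a2 falling by 1.46 on the log2 scale (camera adjusted p = 0.0213, adjusted p = 0.453 with an estimated correlation). Of 17 NAD+ synthesis genes edgeR called Afmid (arylformamidase, which converts N-formylkynurenine to kynurenine), which rose 1.72-fold; 6 had an unadjusted p under 0.05, DESeq2 called 3, limma-voom 1 and the fit with the replicate block 4. For this list the median log2 fold change was -0.15, the mean 0.11, and camera placed it lower (adjusted p = 0.869). In the p53 and senescence list 3 genes rose and 3 fell (4 and 4 adjusted over the list alone), with a median of -0.04 and a mean of -0.1 where camera placed it higher (adjusted p = 0.917). Slc31a1, the high-affinity copper importer, and Lox, a copper-dependent collagen cross-linking enzyme, fell by 0.7 and 0.99 on the log2 scale and were the 2 of 18 metal and copper genes called. edgeR called 0 of 54 oxidative phosphorylation genes, with 9 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. Camera called that list lower (adjusted p = 0.0406, adjusted p = 0.861 with an estimated correlation), a call lost without control replicate 3 (adjusted p = 0.418) and Cu SAC replicate 2 (0.765). It also called the 13 genes of the mitochondrial genome lower (adjusted p = 0.0217, adjusted p = 0.702 with an estimated correlation), a call lost without control replicate 1 (0.115) and Cu SAC replicates 1 (0.113) and 3 (0.105).

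Among called genes whose groups did not overlap and that reached 5 CPM, those with the highest fold changes were Il18rap, Paqr5, Slc4a11, Ccl5, Cxcl1 and Col4a3, and those with the lowest were Kcnt1, Galnt9, Ostn, Nos1, Eln and Sfrp2. Sfrp2, a secreted modulator of Wnt signalling, went from 567 ± 358 CPM in control to 28.4 ± 16.6 CPM with Cu SAC, and Eln (elastin) from 42.3 ± 14.8 to 2.05 ± 1.38 CPM. Il18rap reached 17.3 ± 22.3 CPM, a spread larger than its mean. Of the 430 genes of the first comparison, 276 were also called here in the same direction and 0 in the opposite one. Independent lists would share 27.7. In 20 simulations with no effect 0 were shared, but these called 0.2 genes on average in each comparison, so the count could hardly be higher. The correlation between both sets of log2 fold changes was 0.681 against 0.497 in these simulations, and the covariance 0.4929 against 0.0875. The simulations held no group difference and let genes vary independently. Their values are therefore no measure of what shared controls alone would give in the real libraries. They do not show how far the likeness goes beyond the shared controls. Part of the shared calls may come from the control libraries that both comparisons use, which are too few to split.

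The count of 2085 was 17 and 37 without control replicates 1 and 2 and 3344 without control replicate 3. It was 3559, 339 and 49 without Cu SAC replicates 1, 2 and 3. Of the 68 named genes called in this comparison, 4 kept their calls whichever library was left out, namely Nos1, Saa3, Phgdh and Fabp4. Each of the others lost it without control replicate 1. All but Ostn, Col9a1, Slc16a3 and Tpx2 also lost it without control replicate 2, and all but Icam1, Slc16a3, Tpx2, Ccna2 and Ltbp2 without Cu SAC replicate 3. Their highest adjusted p ranged from 0.054 to 0.16. Without Cu SAC replicate 2 calls lost included those of Afmid, Lox, Eln, Sfrp2, Nos2, Mmp3 and Col2a1.

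Mitochondrial genome genes held 2.43 ± 0.584% of counts in control, 2.53 ± 0.588% in the inflammation group and 1.79 ± 0.359% with Cu SAC (SD, n = 3 each). Differences between groups gave exact two-sided permutation p of 0.8, 0.2 and 0.3 for inflammation against control, Cu SAC against inflammation and Cu SAC against control, where 3 libraries against 3 cannot give a p below 0.1. The first of these differences, 0.099 percentage points, was -0.229 without control replicate 3 and -0.229 without inflammation replicate 3. The 10 most abundant genes held 11.6 ± 0.69%, 10.6 ± 0.471% and 9.79 ± 0.26%, with exact permutation p of 0.2, 0.1 and 0.1 for the same comparisons. Ribosomal protein genes held 1.37 ± 0.0592%, 1.25 ± 0.205% and 1.09 ± 0.162%, with exact permutation p of 0.5, 0.4 and 0.1.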

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

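Fits with 1 surrogate variable, without 2 libraries together, with DESeq2 on the filtered genes, and with a replicate block in the 6 libraries of the first comparison were chosen after the data were seen. In every sentence the values stand in the order inflammation against control, Cu SAC against inflammation, Cu SAC against control, and the cause of a change was not tested unless fewer libraries or genes account for it. Against 430, 8 and 2085 genes, other size factors, limma-voom and leaving out mitochondrial genome genes gave counts within 1.5 times. DESeq2, run on all 27596 genes with its own filtering, gave 1038, 1570 and 3954, and on the 16134 filtered genes 1094, 1670 and 3972. A minimum fold of 2 gave 1144 in the last comparison, and no low-count filter gave 146 for Cu SAC against inflammation, where the stricter filter and the fit of only the groups compared each gave 5. Replicate number as a block gave 1202 and 3910 in the last pair of comparisons. Same-numbered libraries there correlated at 0.4, -0.29 and 0.19 and at 0.28, -0.13 and 0.26. This missed the criterion that every correlation exceed 0.1, so they were not taken as pairs. Whether they share an animal, day or batch cannot be told from this check. The block of the 6 libraries gave 2227 in the first comparison. That block setting changed no list call in the first comparison in the fit of 9 libraries. Elsewhere, it added cartilage matrix (adjusted p = 0.0431), heat shock (0.032) and unfolded protein response genes (0.0431) for Cu SAC against inflammation and macrophage markers (0.045) for Cu SAC against control, and ended the calls of oxidative phosphorylation (0.103) and mitochondrial genome genes (0.0664) there. Without control 3 and inflammation 3, inflammation 3 and Cu SAC 1, and control 3 and Cu SAC 1, in that order, the counts were 228, 3679 and 4683. With the surrogate variable they were 1178, 13 and 111. That variable stood at -0.391, -0.391 and 0.044 in control replicates 1 to 3, -0.273, -0.286 and 0.271 in inflammation, and 0.081, 0.534 and 0.413 with Cu SAC. It thus partly followed the groups, and a fit with it may take out part of the Cu SAC difference itself. Leaving out 1 library gave 77 to 306, 2 to 1392 and 17 to 3559 genes. The count of 4 genes moved back was 195 with DESeq2 (215 on the filtered genes), 38 with no filter, 2 with the stricter filter and with only the groups compared, 128 with the block, 8 with the surrogate variable and 1 to 103 without 1 library. The correlation of -0.026 was -0.024 with upper-quartile factors, -0.36 with DESeq2 on all genes but -0.027 on the filtered genes, -0.028 with limma-voom, -0.397 with no filter, -0.018 with the stricter filter, -0.016 with the block, -0.355 with the surrogate variable and -0.305 to 0.193 without 1 library. Camera with an estimated correlation called 0, 0 and 0 lists, against 11, 12 and 16 with the preset one, and fry called 6, 4 and 13. The difference of 0.099 percentage points in mitochondrial share ran from -0.229 to 0.338 without 1 library.

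Of 4542 log2 fold changes of named genes under the alternatives, 3831 kept direction and side of the threshold, 414 lost and 238 gained a call, and 59 changed sign, 58 of them with neither value past the threshold. Sign changes with the surrogate variable may come from its own difference between the groups. For inflammation against control they were Nos2 -0.32, Mmp3 -0.08, Nnmt -0.13 and Ppargc1a -0.09. Those for Cu SAC against inflammation were Nmnat2 0.15, Adamts4 0.09, Col2a1 0.11, Sod2 -0.08, Mt1 0.43 and Mt2 1.63. Those for Cu SAC against control were Nmnat2 0.34, Adamts5 0.94, Sox9 -0.2, Nmnat1 0.08, Nnmt -0.1, Hmox1 0.29, Nqo1 -0.16, Sod2 -0.24, Mt2 0.21 and Slc30a1 0.1. Nnmt was 0 with no filter for inflammation against control. Mt2, for Cu SAC against inflammation, was 0 with median-of-ratios factors, with DESeq2 and with only the groups compared, 0.26 with limma-voom, 0.01 with the stricter filter and 0.31 with the block. Without 1 library, values for inflammation against control ran from -0.56 to 0.94 for Nos2, -0.57 to 3.14 for Ptgs2, -0.11 to 2.57 for Ccl2, -0.15 to 1.03 for Mmp3, -0.03 to 0.87 for Adamts5, -1.05 to 0.07 for Acan and -0.09 to 0.27 for Nampt. They ran from -0.01 to 0.37 for Sirt1, -0.09 to 0.18 for Sirt3, -0.2 to 0.34 for Nnmt, -0.26 to 0.19 for Ppargc1a, -0.23 to 0.4 for Hmox1 and -0.14 to 0.18 for Slc30a1. For Cu SAC against inflammation they ran from -0.08 to 0.13 for Parp1, -0.2 to 0.03 for Nqo1 and -0.45 to 0.4 for Mt2, and for Cu SAC against control from -0.02 to 0.12 for Sod2. On simulated data 36, 31.6 and 44.9% of 2-fold changes were called at this depth and group size, so uncalled genes may include changes of that size.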

Other observations

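Tests of an NF-κB response, of wrong labels, of a single wrong library behind the rise of p53 targets and of Cu SAC as the cause of the gradient were chosen only after the results were seen. So were the osmoprotective list, the surrogate variable and the fits without 2 libraries together and with DESeq2 on the filtered genes. The other tests were written down after a first look at the calls, the principal components and the lists per library, but before their own values were seen. For lists not described so far in the comparison of Cu SAC with control, 5 of 36 ribosomal protein genes fell and 0 rose, among them Rps24, which fell by 0.55 on the log2 scale (9 lower adjusted over the list alone; camera adjusted p = 5.48e-06, adjusted p = 0.659 with an estimated correlation). In that comparison, 5 of 24 genes of the unfolded protein and amino acid responses fell and 0 rose, among them Phgdh, Atf5 and Asns by 1.6, 1.98 and 1.37 on the log2 scale (14 lower adjusted over the list alone; camera adjusted p = 8.42e-07, adjusted p = 0.352 with an estimated correlation). Of 20 interferon response genes Stat2, Oas1a and Ifi44 rose, by 2.02, 3.4 and 2.7-fold (4 higher adjusted over the list alone; camera adjusted p = 0.00115, adjusted p = 0.659 with an estimated correlation), a list call lost without Cu SAC replicate 1 (adjusted p = 0.183). Of 17 heat shock genes Hspb1 and Cryab, which encode small chaperones, rose 2.83 and 6.92-fold (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0211, adjusted p = 0.659 with an estimated correlation). Of these genes Phgdh kept its call whichever library was left out; each of the others lost it without control replicate 1, control replicate 2 and Cu SAC replicate 3 at least (highest adjusted p from 0.082 to 0.15).

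With 3 libraries a group there are 10 splits of 6 libraries, too few for a share under 0.05. For inflammation against control the real split called 430 genes and the highest other split 0, so 1 of the 10 splits gave as many (edgeR; other splits had 57 to 1814 genes at an unadjusted p under 0.05). For Cu SAC against control the real split called 2085 and the highest other 0, again 1 of 10. For Cu SAC against inflammation the real split called 8 and the highest other 334, so 2 of 10 gave as many. That other split set inflammation replicates 1 and 2 with Cu SAC replicate 1 against inflammation replicate 3 with Cu SAC replicates 2 and 3, which points to a structure of the samples that the groups do not follow.

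The small number of genes called between Cu SAC and inflammation was weighed against 2 libraries that the first principal component placed away from their groups, Cu SAC replicate 1 and inflammation replicate 3; the distances between replicates did so for inflammation replicate 3 but not for Cu SAC replicate 1. Without Cu SAC replicate 1 edgeR called 1392 genes, and without inflammation replicate 3 it called 25. With 1 surrogate variable in the fit, which itself partly followed the groups, it called 13. With Cu SAC replicate 1 and inflammation replicate 3 both left out it called 3679. These counts are consistent with single libraries widening the spread, but leaving out a library that lies near the other group also raises the contrast, and no label says that either library failed, so what the larger counts reflect stays open.

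Of 11 genes linked to the response of cells to salt outside, some through the uptake or making of organic osmolytes, several varied across libraries within groups, but edgeR called 0 in any comparison (lowest adjusted p = 0.058; for Cu SAC against control 4 had an unadjusted p under 0.05, DESeq2 called 4, limma-voom 2 and the replicate block 7, for Cu SAC against inflammation 3, 0, 0 and 2, and for inflammation against control 0 throughout). Slc6a12, a betaine transporter, stood at 0.83 and 0.53 log2 CPM in control replicates 1 and 2 but at 6.4 in control replicate 3. It stood at 1.65 and 1.03 in inflammation replicates 1 and 2 but at 7.33 in replicate 3, and between 7.18 and 9.72 with Cu SAC. Akr1b3, aldose reductase, ran from 5.75 in control replicate 2 to 13.13 in Cu SAC replicate 2. Slc6a6 lay between 7.91 and 8.52 throughout, and Slc5a3 was lower in the Cu SAC libraries (8.33 to 8.58) than in control replicate 3 (9.21). Over 6 of the genes, Slc6a6 and Slc5a3 among them, that had not been looked at when the list was written, the median ranged by 0.6 within control and by 1.2 within the inflammation group, which argues against Cu SAC as the whole cause. Depth and sequence content were also argued against for the gap between inflammation replicate 3 and control replicate 1, the libraries with the highest and lowest list median. Raw counts of the list differed between them by 1.76 log2 units more than the library totals did. That value mostly restates the depth-scaled gap of 1.88. What speaks against depth is that totals differed by at most 1.09-fold among the libraries. Removing each library's trend with GC content and length kept 0.87 of the gap. The list holds members already seen to vary, and the Cu SAC libraries are not part of this gap. A difference in culture conditions such as the salt content of the medium may be involved as a hypothesis; no label records it, and a part played by Cu SAC beside it stays open.

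Of 21 p53 list members 5 were called higher and 1 lower in the inflammation group, a list call lost with an estimated correlation (adjusted p = 0.249), and of 44 members of the NF-κB and chemokine lists 1, or 2.3%, was called higher and 2 lower; the difference between the lists was not tested. In the blocked fit of the 6 libraries 10 of 39, or 25.6%, were higher and 5 lower, and 10 of 21 p53 list members were higher and 3 lower, so the strength of an NF-κB response cannot be told from these tables. A wrong label of 1 library between control and inflammation is argued against. Each of the 6 libraries lay nearer to its own group in at least 77.4% of the genes called without it (lowest for control replicate 3). Replicates 1 and 2 were near alike in each group, so this could not show 2 of them wrong together. Taken without pairs, the median of the p53 list alone does not decide (gap 0.11 between the groups, larger SD within them 0.26). For each replicate number that median was higher in inflammation (0.49, 0.53 and 0.07) than in control (-0.04, -0.09 and -0.3). A single wrong library of any source behind the rise is argued against as well, since 4 to 6 p53 list members were called higher whichever of the 6 libraries was left out. That count, too, could not show 2 near-alike libraries wrong together. For GC content and length, the correction kept 0.99 of the mean fold change of the 6 called p53 list members. That mean was 1.04 on the log2 scale, with Lmnb1, which fell, averaged in. The correction moved genes by a median of at most 0.16 log2 units in any library. Trends that small could hardly account for folds of called genes, so this argues against them for those 6 genes only. The rise of p53 targets may reflect the treatment, its timing or the state of the cultures; none of these was tested.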
